A study of Mus musculus with 15 samples.

How the data were processed

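RNA of 15 mouse cell lines was hybridised to Affymetrix mouse expression arrays, 1 array per line, per the labels' protocols and the series' design text. The value table holds log2 expression values per probe set as deposited by the authors; background correction, summarization, scaling and software are not given in the sources used here. The table carries no detection calls, so a low value cannot be told from background. The authors also deposited a table of their own AKP against AP comparison, with p-values and step-up adjusted p-values, t scores, group means in log2, a linear ratio and a signed fold change, per the file headers. No genome build is named, and no coordinates are printed.

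From the 45101 probe sets, 64 controls were left out, 1 of which had missing values, and 45037 were kept. The platform's gene table gave a single gene for 34945 probe sets, several for 932 and none listed for 9160. Of the single-gene probe sets, 34741 matched a gene of the RefSeq table of GRCm38.p6 by Entrez identifier, with 0 symbols changed; that table was used only for names and for which genes neighbour each other. Each of 18193 genes was represented by the probe set with the highest mean over all 15 arrays. Values were used as deposited, without further scaling or a filter on dim genes.

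Groups came from the genotype label. Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05: AKP against AP over all 15 lines without covariates, female against male with genotype as a covariate, and the line labelled adenoma against the other AKP lines. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 29 lists with at least 5 measured members, beside camera with an estimated correlation and fry. The 30 lists, the tests and the rule for named genes were fixed before the data were examined. The lists cover MAPK output and feedback, EGF family ligands, Wnt/beta-catenin targets, intestinal absorptive and secretory cells, general, squamous and lung epithelium, mesenchymal transition, fibroblast and smooth muscle, haematopoietic, endothelial and mesothelial cells, liver and pancreas, S phase, G2 and M phase, interferon, MHC class I, NF-kB, glycolysis and hypoxia, cholesterol synthesis, ribosome biogenesis, NRF2 targets, the unfolded protein response, TGF-beta targets, YAP, proteases and invasion, and X inactivation and Y-linked genes. In addition, 2 genes and 1 list of the fixed design are not reported here; that list still counts among the 29 tested and the 6 that passed.

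Named genes exclude predicted-gene and clone symbols and need a higher group mean of at least 4.17, the median of all probe-set means. They are the 12 largest log2 differences in each direction among called genes, Apc, up to 4 members of each list with the lowest p (without the limit on brightness), the X inactivation and Y-linked list, and for the adenoma line the 5 genes farthest above and the 5 farthest below the range of the other AKP lines. Other called members of a list, and genes used to describe single lines, were chosen after their values were seen.

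The fit was tested on simulated data with the means and spread of the 18193 genes in the AKP against AP comparison. It recovered 48% of genes changed by 1 on the log2 scale, 66% at 2, 86% at 3 and 80% at 4. Of the calls, 6.67% were false. The simulated noise was drawn independently for each gene, while genes of the real lines move together. The 6.67% is therefore not the share of false calls in the real comparison. Alternatives covered the scaling, the probe set rule, dim-gene filters at the 40th and 60th percentile, the variance model, array weights, covariates, a replicate block, other tests and leaving out each line. Neighbouring genes were compared in windows of 25 genes with a mean of at least 8, in the order of GRCm38.p6, against 1000 shuffles of gene order. The lines were also refitted in 100 splits of the same group sizes, the real one included.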

Results

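The series holds expression arrays of 15 mouse cell lines, 3 with the genotype label AP and 12 with the label AKP. A cell line is a population of cells kept growing in culture. The labels do not spell out the letters and name no tissue, and all lines were grown untreated in the same medium. Each line was measured once, on an array that reads messenger RNA through probe sets, groups of short probes for one transcript. The labels call 11 AKP lines and all 3 AP lines tumour, and 1 AKP line adenoma, a benign growth. They mark 10 lines as female and 5 as male. Deposited log2 values had medians between 3.91 and 4.17 per array, and 35.9% to 39.5% of the probe sets of an array lay below 3, where values crowd on a floor. A difference that starts or ends there depends on that floor. The correlation between lines over 18193 genes ran from 0.874 to 0.980, so no array was a copy of another. It does not show whether some lines came from the same animal or tumour. The labels give a pair number for 1 AP line and 7 AKP lines, each number once. P-values measure the spread between these lines only, and the number of AP lines, 3, limits the precision.

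The comparison of AKP with AP lines asks which genes go with the genotype label. Targets of the MAPK growth signalling pathway and enzymes of cholesterol synthesis were higher in AKP lines, and Igfbp2, Igf2 and Angpt4 were among the lower genes. Itga6, a laminin-binding integrin, was higher by 4.53 ± 0.50 on the log2 scale (SE; limma adjusted p = 6.0e-04), at 13.94 ± 0.49 in AKP (SD, n = 12) against 9.41 ± 1.68 in AP (SD, n = 3), and all 12 AKP lines lay above every AP line. Angpt4, an angiopoietin, lay at 11.20 ± 0.64 in AP and 3.64 ± 0.74 in AKP, a difference of -7.56 ± 0.45 (SE; limma adjusted p = 2.0e-06). Of 18193 genes, limma called 345 at the adjusted threshold of 0.05, 144 higher and 201 lower in AKP, and 261 of them differed by a factor of at least 2. In 224 of the called genes the values of the groups did not overlap, which the call itself favours. Among all genes 2.13% did not, against 0.44% of the possible splits of the lines for a single gene. Genes move together across lines, so these shares do not exclude chance. With the values as deposited, 41.7% of the calls were higher in AKP. With each array centred on its median, which moved the median difference of all genes from 0.012 to 0.12, 61.4% were higher. The share was 62.1% with genes at or above the 60th percentile and 16.3% with array weights.

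Among the genes with the largest differences, Isl1, a homeodomain transcription factor, was higher in AKP by 7.01 ± 1.46 (SE), Ptpn22, a tyrosine phosphatase, by 5.76 ± 0.84 and Cacnb2, a calcium channel subunit, by 5.31 ± 0.89. The potassium channel gene Kcnn4 differed by 4.94 ± 0.99 and the serine protease gene Prss12 by 4.98 ± 1.16. Foxl2os, Mmp10, Gprc5a, Fam110c, St3gal6 and Cdc42ep5 were higher by 5.91, 4.91, 4.06, 3.92, 3.71 and 3.47 on the log2 scale. Limma adjusted p-values of these genes higher in AKP lay between 6.0e-04 for Itga6 and 0.045 for Prss12. For Isl1, Foxl2os and Mmp10, 11 of 12 AKP lines lay above every AP line, and Isl1 lay at 1.98 in AKP 12. In the other direction, Igfbp2, which binds insulin-like growth factors, differed by -8.84 ± 1.91 and the growth factor gene Igf2 by -7.76 ± 1.65. Ldhb, a subunit of lactate dehydrogenase, differed by -5.27 ± 0.66, Tns1, a focal adhesion protein, by -5.27 ± 0.50 and Lbp, which binds lipopolysaccharide, by -6.21 ± 0.74. Myl9, Arhgap24, Ccl9, Prelp, Bnc2 and Pdzrn3 differed by -7.45, -6.57, -5.67, -5.53, -5.49 and -5.37. Limma adjusted p-values of the lower genes lay between 2.0e-06 for Angpt4 and 0.045 for Pdzrn3. Some of the lower genes overlapped between the groups. For Igfbp2, Arhgap24 and Bnc2, 11 of 12 AKP lines lay below every AP line, and for Igf2, Myl9 and Pdzrn3 10 did. Igfbp2 lay at 13.29 in AKP 8 and 8.72 in AP 1. Igf2 lay at 10.14 in AKP 1, 11.17 in AKP 6 and 9.64 in AP 1. Apc, a scaffold protein that limits Wnt signalling, lay at 11.22 ± 0.48 in AP (SD, n = 3) and 11.34 ± 0.30 in AKP (SD, n = 12) and did not pass (limma adjusted p = 0.84). Its probe sets were not placed against any deleted part of the gene, so this does not check the labels.

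Of 17 measured members of the MAPK output and feedback list, 7 rose in AKP and 0 fell, and adjusted over the list alone 12 rose. Dusp6, a phosphatase induced by the pathway, rose by 2.78 ± 0.47 (SE), the ETS factor genes Etv4 and Etv5 by 2.49 ± 0.33 and 2.12 ± 0.40, and the feedback inhibitor gene Spry2 by 1.61 ± 0.33. Spred2, Phlda1 and Epha2 rose by 1.59, 1.70 and 3.22. The list passed camera (adjusted p = 4.1e-10), and the adjusted p = 0.032 with an estimated correlation. Of 15 measured members of the cholesterol synthesis list, 5 rose and 0 fell, and adjusted over the list alone 13 rose. Srebf2, the transcription factor of the pathway, rose by 1.35 ± 0.15, Idi1 by 2.08 ± 0.34, Dhcr7 by 1.45 ± 0.25, and Fdft1 by 1.16 ± 0.21. The fifth was Msmo1, at a mean of 12.25 in AP and 13.76 in AKP. The list passed camera (adjusted p = 6.8e-13), and the adjusted p = 0.039 with an estimated correlation. The lists were also tested without the lines AP 1 and AKP 1, a choice made after seeing the data. The camera adjusted p with an estimated correlation was then 0.21 for the MAPK list and 0.26 for the cholesterol list. At the preset correlation it was 6.0e-07 and 2.2e-07, with 6 and 4 members called higher. With an estimated correlation, 2 lists passed with all lines, and 0 passed when AP 1, AP 2 or AP 3 was left out. With all lines 0 passed with each array centred on its median or with genes at or above the 60th percentile. With sex or the pair label as a covariate, with array weights, or with genes at or above the 40th percentile, 1 passed. The same count of 1 came without AKP 1, AKP 5, AKP 7, AKP 8 or AKP 10.

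**Figure D1:**
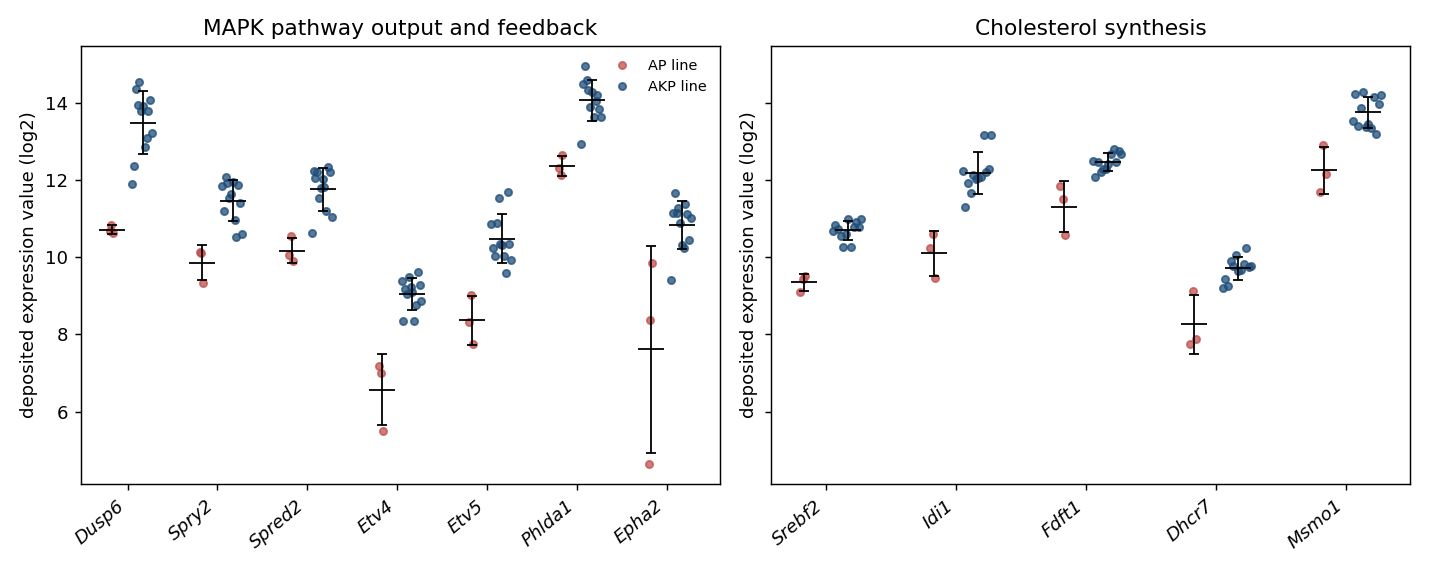
Deposited log2 expression values of the called members of the MAPK output and feedback list (left) and of the cholesterol synthesis list (right), 1 point per cell line, with black bars for the group mean and SD (AP, n = 3; AKP, n = 12). Dusp6 averages 10.71 in AP and 13.50 in AKP lines, and Srebf2 9.36 and 10.71.

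Camera with the preset correlation passed 6 of 29 lists, 3 higher and 3 lower in AKP, while random splits of the lines into 3 and 12 passed a median of 6 lists, so this count says little by itself. Of the ribosome biogenesis and MYC list, 1 of 17 members rose, Nop16 by 1.11 ± 0.25, with 3 adjusted over the list alone; the list's adjusted p = 2.6e-04 became an adjusted p = 0.81 with an estimated correlation. Of the type I interferon list, 0 of 14 members passed and 2 did adjusted over the list alone. Its median difference was -2.92, with Ifit1 at -6.06 and Ifit3 at -4.40, and the list's adjusted p = 4.7e-06 became an adjusted p = 0.73 with an estimated correlation. The interferon list's median level was high in AP 1 (9.55), AP 2 (8.94) and AKP 1 (9.80), lay at 6.44 in AP 3 and was at most 4.53 in the other AKP lines. With the 10 AKP lines matching the authors' deposited means, chosen after seeing the data, 6 of its members fell. The list's camera adjusted p with an estimated correlation was 0.077 there. With those lines against AP 2 and AP 3, 2 members fell (0.15), and without AP 1 and AKP 1, 1 fell (0.21). Of the fibroblast and smooth muscle list, 2 of 18 members fell, Col1a1, a fibrillar collagen, by 5.02 on the log2 scale and Lum by 0.54, the latter between means of 3.01 and 2.47 on the floor, and 3 fell adjusted over the list alone. The fibroblast list's median level was 13.3 in AP 1 and 12.3 in AKP 1, 4.48 in AP 2 and 5.95 in AP 3, and at most 7.54 in the other lines. That list's adjusted p = 4.1e-04 became an adjusted p = 0.73 with an estimated correlation. With the 10 AKP lines matching the authors' deposited means against AP 2 and AP 3, chosen after seeing the data, it was 0.049, and without AP 1 and AKP 1 alone 0.81.

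The lists of proteases and invasion, mesenchymal transition and YAP did not pass camera. In the proteases and invasion list 3 of 16 members rose, Itga6, Plaur (2.42 ± 0.41) and Mmp10 (4.91 ± 0.98), and adjusted over the list alone 3 rose and 2 fell; the list's adjusted p was 0.36. Zeb1, a repressor of epithelial genes, fell by 1.34 ± 0.27 as the only called member of the mesenchymal transition list (adjusted p = 0.36), where 3 members fell adjusted over the list alone, and Amotl2 fell by 1.56 ± 0.34 as the only called member of the YAP and regenerative epithelium list (adjusted p = 0.38), as it was adjusted over the list alone.

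The following lists did not pass camera, and limma called 0 of their members over all genes. Adjusted over the list alone, 1 member of the endothelial list fell, 1 member of the NRF2 list rose and 1 fell, and 0 members of the others among these lists passed. Among signalling lists, the EGF family ligands had a median log2 difference of 1.11 (camera adjusted p = 0.38) and the Wnt/beta-catenin targets one of 0.76 (0.50). The TGF-beta targets had a median of -0.10 (0.95) with a positive camera direction, and the NF-kB and inflammatory cytokines one of -0.10 (0.53). Among epithelial lists, the medians were 0.48 for intestinal absorptive cells (0.38), 0.31 for general epithelium (0.71), 0.11 for squamous (0.79) and -0.04 for lung epithelium (0.38). The intestinal secretory list had a median of 0.06 and a mean of -0.48 (0.95). Markers of other cell types had medians of 0.02 for haematopoietic (0.95), -0.04 for endothelial (0.47), 0.14 for mesothelial (0.68) and 0.0020 for liver and pancreas genes (0.82). The haematopoietic and the liver and pancreas list had a negative camera direction. For S phase the median was 0.38 (0.36), for G2 and M phase 0.18 (0.72) and for glycolysis and hypoxia 0.32 (0.38). MHC class I presentation had a median of -0.52 (0.36), NRF2 targets one of -0.69 (0.53) and the X inactivation and Y-linked list one of -0.99 (0.54). The unfolded protein and integrated stress response list had a median of 0.10 and a negative camera direction (0.95).

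Lines AP 1 and AKP 1 had the lowest median correlations with the other lines, 0.892 and 0.922. Krt18, a keratin of simple epithelium, lay at 3.62 in AP 1 and 10.82 in AKP 1, and Axin2, a Wnt target, at 4.09 and 6.04, against 11.74 and 12.77 in the other AP lines. Other lines shared part of this: Krt18 lay at 8.93 in AKP 8, Krt8 at 4.27 in AKP 10, and Cdh1 at 5.71 in AKP 8 and 5.89 in AKP 10. The stromal-type genes Col3a1, Pdgfrb and Acta2 lay at 12.57, 10.98 and 12.35 in AKP 8. The collagen gene Col1a2 lay at 15.49 in AP 1 and 12.60 in AKP 1 and at 4.72 or lower in the other lines. AP 1 correlated best with AKP 1 (0.936 over genes, which are not independent replicates). Without both lines 503 genes were called, 170 higher and 333 lower in AKP, and 210 of the 345 genes were among them; this alternative was chosen after seeing the data.

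**Figure D2:**
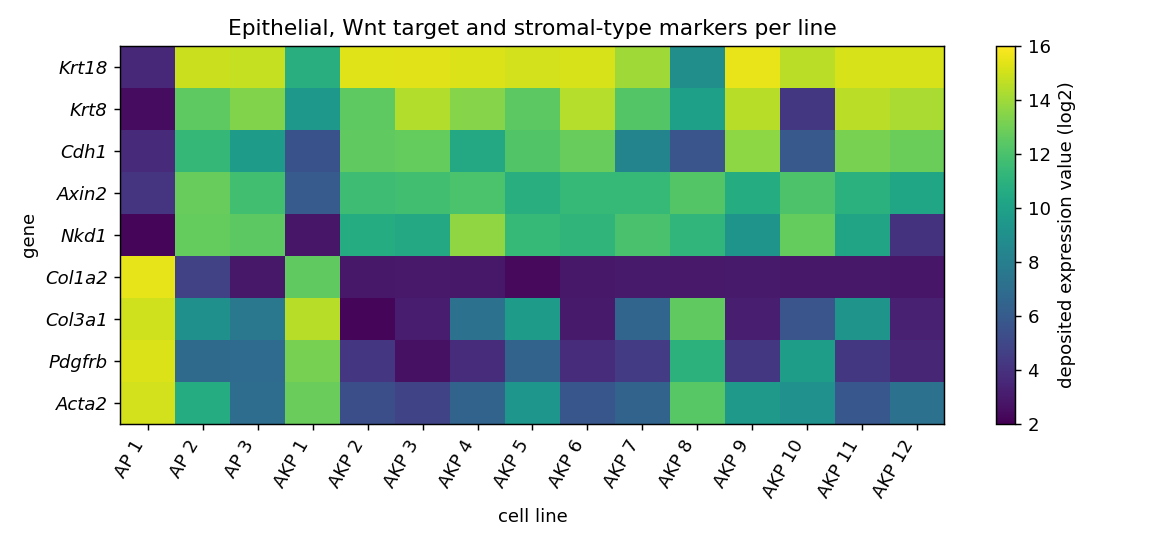
Deposited log2 expression values (colour) of epithelial genes (Krt18, Krt8, Cdh1), Wnt targets (Axin2, Nkd1) and stromal-type genes (Col1a2, Col3a1, Pdgfrb, Acta2) in each of the 15 cell lines. Col1a2 reaches 15.49 in AP 1 and 12.60 in AKP 1 and stays at or below 4.72 elsewhere.

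The series' design text counts 10 AKP lines where 12 are listed here. The group means in the authors' deposited table, which holds 501 entries, matched the means of 10 AKP lines without AKP 1 and AKP 8: for 409 of 410 genes compared, each by its closest probe set, the summed difference of both means was under 0.02 log2. The next best of 66 choices of 10 lines matched 61 genes. With those 10 AKP lines, chosen after seeing the data, limma called 728 genes, 338 higher and 390 lower, and 336 of the 345 genes were among them. Of the 410 genes, 405 had the sign of the authors' deposited table with all 12 AKP lines and 184 passed the threshold; with the 10 lines 326 passed.

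Genes that neighbour each other on a chromosome were also compared, a choice made after seeing the data. On chromosome 2, Pdrg1 differed by -2.43 ± 0.31 (SE), Tbc1d20, a GTPase-activating protein, by -2.12 ± 0.26 and Kif3b, a kinesin motor, by -1.98 ± 0.33. They lie in a stretch of 25 bright genes from Nanp to Pxmp4, of which 24 had the higher mean in AP and 9 were called. On chromosome 12, Fam110c opened a stretch of 25 genes ending at G2e3, of which 3 were called and 1 had the higher mean in AP.

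**Figure D3:**
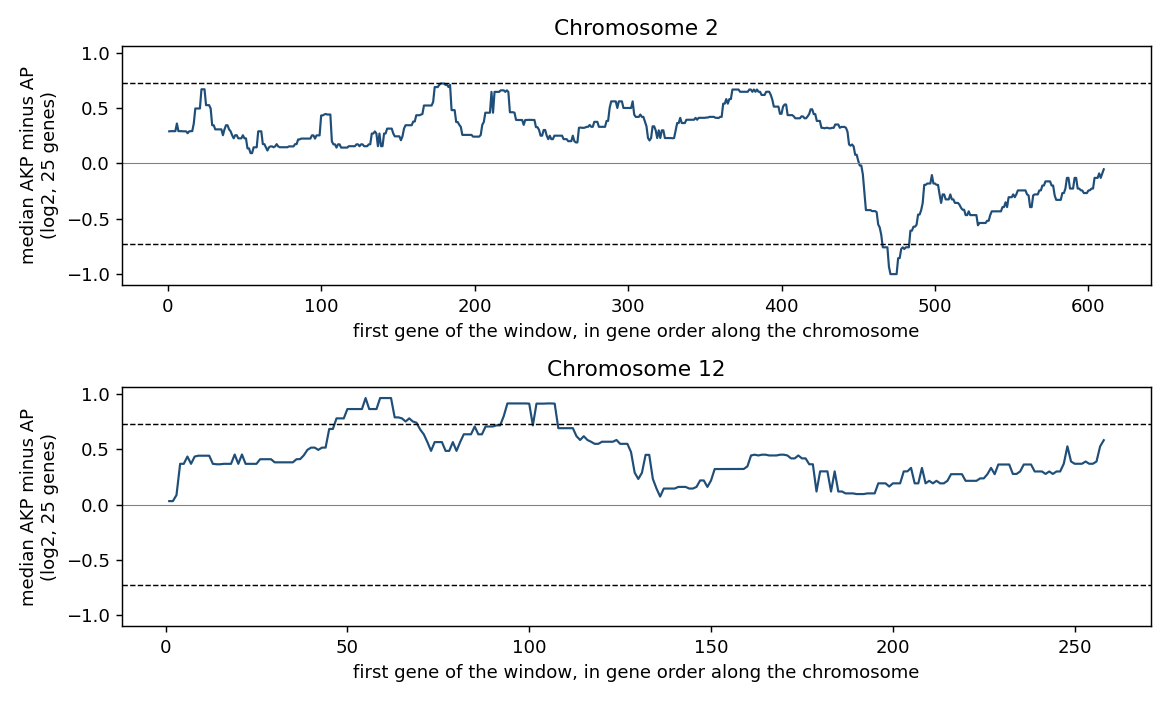
Median log2 difference AKP minus AP (vertical axis) in running windows of 25 neighbouring bright genes, against the place of the window's first gene in gene order (horizontal axis), on chromosome 2 (top) and chromosome 12 (bottom); dashed lines give the 95% limit of shuffled gene orders, 0.72. The median falls past the lower limit once on chromosome 2 and rises to 0.96 on chromosome 12.

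The labels also give the sex of each line, and the fit with genotype as a covariate asks which genes go with it. Limma called 0 of 18193 genes between lines labelled female and male; 574 had an unadjusted p under 0.05. Xist, the RNA that silences an X chromosome, lay at 9.34 ± 4.50 in lines labelled female (SD, n = 10) and 2.76 ± 0.16 in lines labelled male (SD, n = 5). The Y-linked gene Eif2s3y lay at 4.63 ± 3.30 and 10.02 ± 3.82, and the Y-linked gene Kdm5d at 3.92 ± 2.33 and 8.34 ± 2.93. Uty and Tsix differed by -1.22 ± 0.40 and 0.02 ± 0.08 (SE, female minus male). These genes went against the label of several lines. The line labelled female as AKP 11 had Eif2s3y at 12.71 and Xist at 2.67, the line labelled female as AP 3 had Eif2s3y at 8.47 and Xist at 3.21, and AKP 2, labelled female, had neither. AKP 5, labelled male, also had neither, with Eif2s3y at 3.24. The sex comparison rests on these labels.

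**Figure D4:**
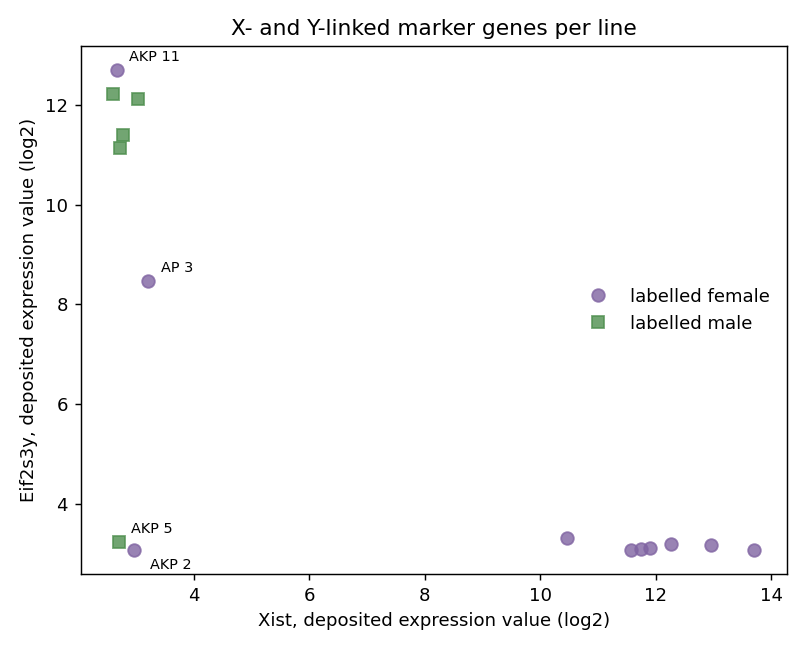
Deposited log2 expression values of the X-linked Xist (horizontal axis) and the Y-linked Eif2s3y (vertical axis) in the 15 cell lines, 1 symbol per line, shaped and coloured by the labelled sex. AKP 11, labelled female, sits at 12.71 for Eif2s3y among the lines labelled male, and AKP 5, labelled male, sits at 3.24.

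Only AKP 6 carries the adenoma label, so its difference from the 11 AKP tumour lines has no replicate check. Apob, an apolipoprotein, lay at 14.22 in AKP 6 and at 3.66 ± 1.16 (SD, n = 11) in the tumour lines, whose highest value was 7.04. Klhl29, Kctd12b, Krt27 and Aqp9 lay above the highest tumour line by 4.73, 4.48, 3.86 and 3.47 on the log2 scale. Cdc42ep3, Rab10os, Tfpi, Clybl and Plcb1 lay below the lowest tumour line by 2.44, 2.43, 1.98, 1.75 and 1.60. Limma called 22 genes in AKP 6, all of them higher, which was the lowest count among the 12 AKP lines. The same fit with each tumour line in its place called between 33 and 590 genes, with 590 in AKP 1.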

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

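The tests of the sex labels in this part were chosen after the result was seen. Among 10 checks of a single line far from its group (5 sex-linked genes in 2 labelled sexes), 5 stood out. The limit is set for about 1 in 20 by chance in a single check. The checks share lines and linked genes and are not independent, so the count of 5 is not a test. Among the 5 lines labelled male, AKP 5 lay at 3.24 for Eif2s3y and 3.11 for Kdm5d, against at least 11.14 and 9.31 in the others. Among the 10 lines labelled female, AKP 11 lay at 10.05 for Kdm5d, against at most 5.74. Tsix stood out in AKP 5 (2.26) and AKP 12 (2.56), both on the floor of the arrays. Eif2s3y in AKP 11 was 0.95 log2 above the median of the male-labelled lines that express it, which a wrong sex label or an exchanged line needs, but the Y-linked Uty lay at 3.83 in AKP 11, against 4.63 to 7.42 in those lines. On the values of AKP 5 alone, an exchange of AKP 5 and AKP 11 cannot be told apart from a lost Y chromosome in AKP 5. Xist in AKP 5 was 2.70, and AKP 2, labelled female, lacks Xist too. A lost Y chromosome in AKP 5 would leave the Y-linked genes of AKP 11 unexplained. No biological explanation was tested.

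A difference of the genotype effect between the sexes passed limma for 366 genes, but it rests on 1 AP line labelled female, AP 3, whose sex genes go against its label. Among the named genes, the effect (AKP minus AP, female minus male lines) was -3.43 for Mmp9, -1.95 for Wt1 and -0.64 for Egf on the log2 scale.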

How the results depend on the processing

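The count of 345 genes between AKP and AP was 195 with genes at or above the 60th percentile and 153 with array weights. It was 181 with a Welch statistic per gene and 582 over single probe sets. With the pair label, a number given or not, as a covariate, the count was 440, and 306 of the 345 genes were among those. Chosen after seeing the data, it was 728 with the 10 AKP lines matching the authors' deposited means and 647 with those against AP 2 and AP 3. Leaving out 1 line gave 177 (without AP 3) to 584 genes (without AP 2), with 540 without AKP 8, 224 without AKP 5, 219 without AKP 11 and 216 without AKP 6, the adenoma-labelled line. Of the 345 genes, 182 stayed called without AP 1, 231 without AP 2, 122 without AP 3 and 112 with array weights. The 6 lists became 2 with an estimated correlation and 2 with fry, and 3 to 8 leaving out 1 line, the 3 without AP 1. Leaving out 1 line gave 0 to 1 genes between the sexes, the 1 being Frzb (-4.43, limma adjusted p = 0.013) without AKP 5. The 22 genes of the adenoma line became 34 with quantile normalization, 5 at or above the 40th percentile and 93 over single probe sets, and 16 to 31 leaving out 1 line. The cause was not tested. With replicate numbers 1 to 3 as a block, 0 genes and 8 lists were called. There the G2 and M phase list turned to a median of -1.84. The unfolded protein list passed with a median of 0.95 and a positive camera direction, negative with all lines. Deviations of same-numbered lines correlated at 0.45, 0.01 and -0.12. AP 1 matched AKP 1 best, while AP 2 and AP 3 matched AKP 3 and AKP 6 best. A pairing by number is thus not seen for numbers 2 and 3 and stays open for number 1. Other probe sets of Bnc2 (0.030) and Zeb1 (0.035) reversed the sign near 0. The 39 named genes called with all lines gave 1154 values under alternatives, of which 889 stayed called, 263 did not and 2 reversed. The 99 others gave 2897 values, of which 70 were called. Floors for linear values were not run, since the table is log2. Low signal over background limits genes on the floor.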

Other observations

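The tests on AP 1 and AKP 1, on sex splits and on neighbouring genes, except the one on scaling, were chosen after the result was seen. On chromosomes chosen after their values were seen, and without a test against chance, called genes went one way. On chromosome 19 all 17 called genes were lower in AKP lines and on chromosome 18 all 11, while on chromosome 14 all 12 were higher. Chromosome 2 held 54 of the 345 called genes, 3.86% of its 1399 tested genes, against 1.90% of all genes. Golt1b was measured by probe sets that differ: one was higher in AKP by 6.37 ± 0.47 (SE) and the other, the brighter one, differed by -0.14 ± 0.27, a gene chosen after its values were seen.

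In windows of 25 neighbouring bright genes, a stretch of chromosome 2 from Nanp to Pxmp4 had a median difference of -0.999 and a stretch of chromosome 12 from Fam110c to G2e3 one of 0.96. Of 1000 shuffles of gene order, 0 gave a window as extreme as either, and weaker stretches on chromosomes 4 and 9 also passed the 95% limit of 0.72. The smaller of both medians was still 0.90 with quantile normalization, and 0.86 without AP 1 and AKP 1. Scaling acts on whole arrays and would hardly single out neighbouring genes, so the first value tests it little. The second shows that the stretches do not rest on AP 1 and AKP 1 alone. On chromosome 2, AP 1 showed the stretch least of the AP lines, so leaving it out could hardly weaken it there. Of 100 splits of the lines, 3 gave a window as extreme, the real one included, and the highest other was 1.04. The others had AP 1, AP 3 and AKP 8, and AP 2, AP 3 and AKP 12, as the small group. Both hold mostly AP lines, so genotype and a structure of the lines cannot be told apart in them. The splits do not firmly exclude chance. A copy number or strain difference between the lines may be the source, but without DNA measurements this hypothesis cannot be told apart from others. On chromosome 2, 11 of 12 AKP lines lay beyond every AP line. Relative to the AKP mean, the median of that stretch lay at 1.19 in AP 2 and 1.65 in AP 3. It lay at 0.34 in AP 1, below AKP 7 at 0.43. On chromosome 12, AP 2 at -0.45 lay just above AKP 8 at -0.46. Thus not every AP line stood apart in these stretches.

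In AP 1, 8 epithelial markers, kept for a high mean in the other 13 lines, lay a median of 7.75 log2 below those lines. The quartiles of the drop were 4.37 and 9.91. This is more than stromal-type cells would give in a mixture with at least 1 in 8 cells epithelial, a bound set afterwards. A mixture with fewer epithelial cells is not excluded. Epcam (9.82 in AP 1) was not lower, and AKP 8 and AKP 10, among the 13, were low in some markers too. In AKP 1 the median drop was 3.82, which leaves a partial admixture open: it cannot be told apart from a whole culture of another cell state. An exchange of AP 1 and AKP 1 with each other is argued against by Xist, which was 9.55 log2 higher in AKP 1, labelled female, than in AP 1, labelled male. A culture of stromal-type cells, or tumour cells in a mesenchymal state, may fit AP 1. AKP 1 kept Krt8 at 9.49, Krt18 at 10.82 and Krt19 at 10.76, with Cdh1 at 5.54 and Esrp2 at 3.74. Its markers thus go both ways, which does not settle which cells the culture holds. No biological explanation was tested.

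Chance was tested by refitting 100 splits of the 15 lines into 3 and 12. As many genes as the real 345 were called in 2 of them, the real one included, the highest other being 352 with AP 1, AP 3 and AKP 8 as the small group. A split with AP 1, AP 3 and AKP 1 called 333. Both hold 2 of the 3 AP lines, so genotype and a structure of the lines cannot be told apart in them. AP 1 and AP 3 gave 14 genes with AKP 2 and 1 with AKP 10. AP 1 with AKP 1 and AKP 2 gave 219, and the median of the other splits was 0. The splits do not firmly exclude chance. As many lists as the real 6 were called in 64 splits, with up to 15, so chance cannot be excluded for that count. The median of the MAPK list was as large as the real 1.59 in 1 split, the real one (highest other 1.16), and that of the cholesterol list as large as 1.22 in 1 (highest other 0.89). Those highest others had AP 2, AP 3 and AKP 12, and AP 1, AP 3 and AKP 2, as the small group, so they too hold 2 of the 3 AP lines. The interferon list reached 2.92 in 2 splits (highest other 3.46) and the ribosome biogenesis list 0.65 in 3 (highest other 0.76). These counts treat each list alone, with no allowance for the 29 lists tested, so they do not firmly exclude chance. The fibroblast list reached 2.42 in 8 (highest other 4.69), so chance cannot be excluded. For sex within genotype all 100 splits called at least the real 0 genes, the highest other being 12; a real count of 0 fixes that outcome, so it decides nothing.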
